A study of Rattus norvegicus with 12 samples.

How the data were processed

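Total RNA was extracted with TRIzol from liver pieces of about 20 mg of 12 male obese Zucker rats, 6 per diet, killed on day 29 of the feeding trial. Rats were 5 to 6 weeks old at the start and weighed 277 ± 23 g (control) and 279 ± 23 g (PSC; SD over the 12 rats of each feeding group). Across the 12 samples the RNA integrity number was 8.01 ± 0.38 and the ratio of absorbance used for purity was 1.90 ± 0.01, per the labels' protocols. The labels give no integrity value per sample. Biotin-labelled RNA was hybridised to the arrays (Affymetrix, Rat Gene ST, version 2.0).

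The deposited values are log2 signals per transcript cluster, made by the authors with Affymetrix Expression Console and RMA, per the submitters' processing notes. RMA corrects the background, quantile normalizes the arrays and summarises probes by median polish, so that array medians are nearly equal and small changes of dim genes are compressed. Software versions, library files and filters are not given in the sources used here, nor are detection calls, so that absence of a transcript cannot be stated. The values were used as they stand, with no further normalization in the main analysis.

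Genes were named through the platform annotation: 18511 transcript clusters have 1 gene symbol, 575 have several and 11261 have none in the table used. Only clusters with 1 symbol were tested. Of these, 18394 matched a RefSeq gene of the rat assembly GRCr8 by gene number and 0 symbols differed after the match. That assembly served for names and for which genes neighbour each other, and no coordinates are printed because the array's build is not given in the sources used here. A gene with several clusters, which holds for 291 genes, was represented by the one with the highest mean signal over the 12 arrays, and for 4 genes such clusters moved in opposite directions at unadjusted p below 0.05. This left 18166 genes. Some genes are not reported here.

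Groups were taken from the sample titles and conditions. Diets were compared with a linear model per gene and empirical Bayes moderation (limma 3.58.1 with statmod 1.5.0 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A looser count took unadjusted p below 0.05 with a fold of at least 1.3. Gene lists were tested against the other genes with camera at a preset correlation of 0.01 between genes, adjusted over the 33 lists, and again with the correlation estimated from the data and with fry. The lists hold 710 fixed members, of which 614 were measured as single-symbol genes, 2 of them found through a synonym, and 25 genes stand in more than 1 list. A list's score on an array is the mean of its genes' log2 signals after centring each gene over the 12 arrays. Scores and array-wide measures were compared by exact two-sided permutation over all 924 assignments of the arrays. The separation of the diets was tested over 462 splits, counting those with a difference in distance as large or larger. Figures were drawn with matplotlib 3.10.9.

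The genes named in the text follow a rule set before the data were examined, as were the lists, the main tests and most alternatives. The rule takes the 12 largest rises and 12 largest falls in log2 fold change among genes with an adjusted p below 0.05. It also takes, for each list, the 2 to 4 members with the smallest p. Symbols that are only LOC or RGD numbers were passed over. Other genes given with values were named after these were seen. They are changed members of a list counted in the text, the weakest stellate marker and a gene with only a number for a symbol. The rest belong to gene families or neighbouring pairs described under other observations.

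The test was checked on simulated data with the means and spreads of these 18166 genes. The noise was drawn independently for each gene and array, so the shares below may differ for real arrays, whose genes are correlated. It recovered 82% of 100 genes changed by 0.5 on the log2 scale, 99% of 100 genes changed by 1 and 60% of 20 genes changed by 0.3. Of its 203 calls 10, or 4.93%, fell on unchanged genes.

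Alternatives tried were all transcript clusters in place of named genes, a filter on dim genes, another quantile normalization, median centring, a variance prior with trend, array weights, the replicate number as a block, the mean of a gene's clusters, a threshold of 0.1, a fold of 1.5, Euclidean distance for the separation of the diets, and leaving out each array. Added after seeing the data were cyclic loess normalization, leaving out PSC replicates 2 and 5 together, and exact permutation of list scores. Which rats shared a cage is not given in the sources used here, so cages could not enter the model.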

Results

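Liver RNA from 12 male obese Zucker rats, a strain that carries 2 defective copies of the leptin receptor gene, was profiled on Affymetrix Rat Gene 2.0 ST arrays, with 1 rat per array. Of these rats, 6 had eaten a control diet and 6 a diet of like energy and nutrient content that held 5% PSC, the labels' name for the supplement. The series title describes a biotechnologically produced oyster mushroom and asks for its physiological effects in the liver. Feeding lasted 4 weeks in groups of 12 rats, and the 6 profiled rats of each group were drawn at random. The deposited values are log2 signals of 30347 transcript clusters. The arrays had median log2 signals between 4.71 and 4.85 and correlated with each other at 0.987 to 0.995 across genes. The number of arrays limits the precision, and rats shared cages in pairs, so that cage mates among the profiled rats would not be fully independent.

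The PSC diet was accompanied by more genes that fell than rose in the liver. Of 18166 genes tested, 343 were lower and 130 higher in PSC-fed rats (limma, adjusted p below 0.05, n = 6 per diet). Sult2a1, a sulfotransferase that conjugates steroids and bile acids, rose 4.98-fold, and Cyp2c55, a cytochrome P450, fell 5.60-fold. Of 20 markers of stellate cells and fibrosis 8 fell, Dcn and Mmp2 among them, and the shift of this list was not called with an estimated correlation between genes (adjusted p = 0.151). Dgat2 of triglyceride synthesis rose and the sterol synthesis gene Dhcr7 fell. Most changes were small: the median absolute log2 fold change of the changed genes was 0.415, and 25 of them reached a fold of 2, with 3 higher (Sult2a1, Car3 and LOC100360095) and 22 lower. Without overlap between the diets were 244 of the changed genes, and 398 of all genes, which is 2.19% where chance gives 0.216%. At unadjusted p below 0.05, 3470 genes passed, and 501 of these had a fold of at least 1.3, with 147 higher and 354 lower.

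The diets also separated the arrays as a whole. In an exact two-sided permutation test over the 462 splits of the arrays into groups of 6, no other split gave distances as large between the groups against within them (p = 0.00216, the smallest these splits can give). The first principal component held 27.2% of the variance. Its scores averaged -11.0 ± 6.18 in controls and 11.0 ± 7.18 in PSC-fed rats (SD, n = 6). PSC replicate 4 lay nearest to the controls on it, at -1.57. On the second component, with 16.2% of the variance, PSC replicates 2 and 5 stood highest, at 21.2 and 11.7. PSC replicate 4 followed them among the PSC arrays at 3.43, and PSC replicates 1, 3 and 6 lay at -10.1 or below.

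**Figure D1:**
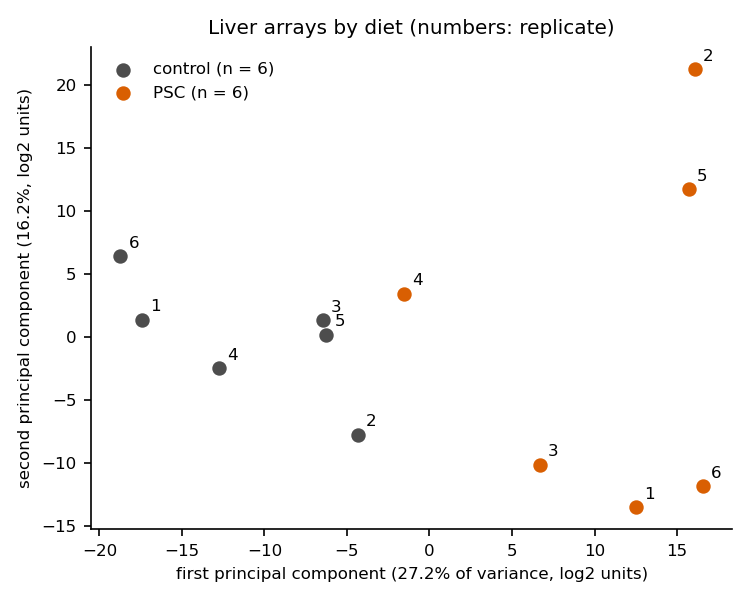
Scores of the 12 arrays on the first (horizontal) and second (vertical) principal component of the log2 signals, with 27.2% and 16.2% of the variance; each point is 1 array, grey for control and orange for PSC, numbered by replicate. The 6 controls lie to the left of the 6 PSC arrays, with PSC replicate 4 nearest to them at -1.57.

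The count of changed genes depended on single arrays, and moved by more than 1.5 times without any of 9 of them. It was 142 without control replicate 1, 252 without control replicate 3, 164 without control replicate 4, 298 without control replicate 5 and 188 without control replicate 6. It was 206 without PSC replicate 1, 199 without PSC replicate 5, 160 without PSC replicate 6 and 735 without PSC replicate 4.

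The 12 genes with the largest rise were led by Sult2a1. It (transcript cluster 17629978) went from 4.53 ± 0.63 in controls to 6.84 ± 0.67 in PSC-fed rats (mean log2 signal ± SD, n = 6), a log2 fold change of 2.32 (SE 0.31, adjusted p = 0.0041) with all 6 PSC arrays above every control. Car3, the muscle and liver carbonic anhydrase, rose by 1.46 (SE 0.26, adjusted p = 0.0133), and Gstp3, a pi-class glutathione transferase, rose by 0.93 (SE 0.14, adjusted p = 0.0041). The glucuronosyltransferase Ugt2b1 was higher by 0.88 and the macrophage haemoglobin scavenger receptor Cd163 by 0.87. Inhbc, which encodes an activin subunit made in liver, went from 8.77 ± 0.41 to 9.59 ± 0.17. Cpt1a, which commits long-chain fatty acids to mitochondrial oxidation, rose by 0.81 (SE 0.19), Gpt, which encodes alanine aminotransferase, by 0.80 (SE 0.20), the calcium-binding protein gene Rgn by 0.76 (SE 0.19) and Srebf1, the lipogenic transcription factor, by 0.72 (SE 0.14). The microRNA gene Mir291b was higher by 0.72. The olfactory receptor gene Or5aq1d rose by 0.93 from a log2 signal of 2.73, in the dim range of the array. LOC100360095, named here after its values were seen because it has only a number for a symbol, rose by 2.06 (SE 0.43, adjusted p = 0.0266). Of the 12 rises, 5 (Sult2a1, Car3, Gstp3, Inhbc and Mir291b) stayed past the threshold whichever array was left out, whereas Or5aq1d lost it in 1 of the 12 such fits, Ugt2b1 and Srebf1 in 4, and Cd163, Cpt1a, Gpt and Rgn in 8, 8, 10 and 9.

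The 12 largest falls were led by Cyp2c55. It (transcript cluster 17641955) went from 9.93 ± 0.23 to 7.44 ± 1.37 (mean log2 signal ± SD, n = 6), a log2 fold change of -2.49 (SE 0.47, adjusted p = 0.0159), with a wide spread among the PSC-fed rats. Tsx, a testis-specific X-linked gene, changed by -2.03, and Abcb1b, a P-glycoprotein efflux pump, by -1.94 (SE 0.35, adjusted p = 0.0133). The macrophage elastase gene Mmp12 changed by -1.90 (SE 0.33, adjusted p = 0.0109). Gstm3, a mu-class glutathione transferase, went from 9.92 ± 0.37 to 8.36 ± 0.46. Fabp4, the fatty acid binding protein of adipocytes and macrophages, fell from 6.35 ± 0.36 to 4.85 ± 0.56. The serine protease gene Prss8 and the oncostatin M receptor gene Osmr changed by -1.49 and -1.46. Serpina7, which encodes thyroxine-binding globulin, changed by -1.41 (SE 0.32), the oxidised LDL receptor gene Olr1 by -1.40 (SE 0.29), and the caspase gene Casp12 by -1.38 (SE 0.19). Parm1, an androgen-regulated mucin-like gene, changed by -1.36 (SE 0.13), with the smallest adjusted p of all genes tested, 0.00039. All but Serpina7 and Olr1 of these falls, 10 of 12, stayed past the threshold with any 1 array left out. Probes for Cyp2c55, Gstm3, Gstp3, Abcb1b, Sult2a1 and Or5aq1d may also bind transcripts of close relatives of these genes.

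**Figure D2:**
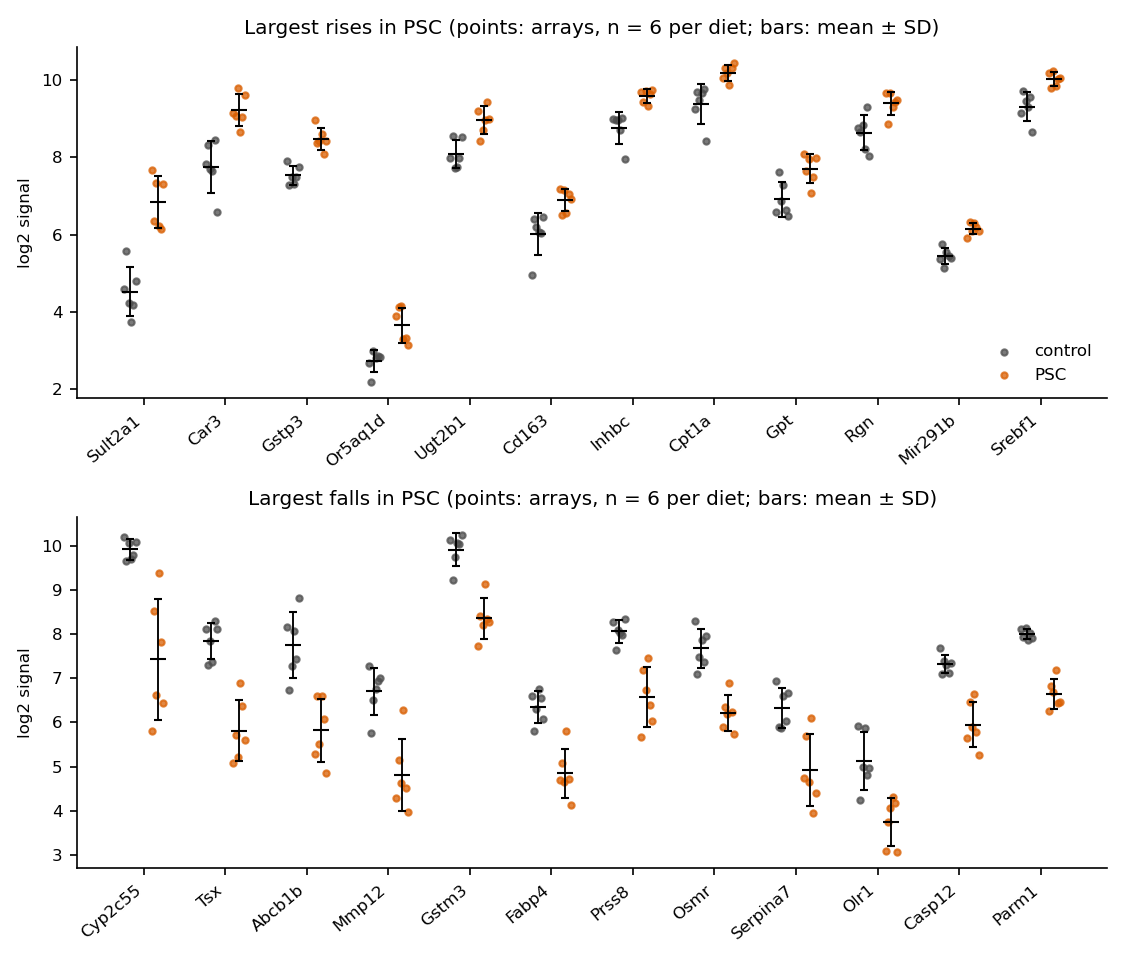
Log2 signal (vertical) of the 12 genes with the largest rise (upper panel) and the 12 with the largest fall (lower panel); points are single arrays, grey for control and orange for PSC, and bars give the mean ± SD of 6 arrays. Sult2a1 goes from 4.53 to 6.84 and Cyp2c55 from 9.93 to 7.44, and the 6 PSC arrays lie clear of the 6 controls for 9 of the rises and 8 of the falls.

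Markers of stellate cells and fibrosis shifted lower as a list (camera, median -0.34, adjusted p = 6.47e-13, and adjusted p = 0.151 with an estimated correlation). Of 20 measured members, 8 fell and 12 did not pass over all genes tested, and 13 fell when adjusted over the list alone. Dcn, which encodes the matrix proteoglycan decorin, went from 6.39 ± 0.22 to 5.51 ± 0.41 (log2 signal ± SD, n = 6), and Mmp2, a gelatinase, from 6.15 ± 0.09 to 5.50 ± 0.28. Loxl1, a collagen cross-linking enzyme, and Col1a2, a type I collagen chain, changed by -0.55 and -0.58, and Tagln, Fbn1, Rgs5 and Col3a1 also fell, by 0.92, 0.55, 0.48 and 0.30 on the log2 scale. Every one of the 20 members had a negative value, the weakest -0.0017 for Col5a1. PSC replicate 4 lay below every control for Dcn, Mmp2 and Loxl1, and within the controls for Col1a2 (6.72). Its mean score for the list, 0.0784, also lay within the range of the controls. The other PSC arrays lay at -0.191 or below and every control at 0.0519 or above.

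Of the 33 lists fixed before the data were examined, 13 were shifted by camera with a preset correlation of 0.01 between genes, 6 higher and 7 lower. With correlations estimated from the data camera called 0 of them (lowest adjusted p = 0.151), and 4 had an unadjusted p below 0.05. Fry, which tests each list by itself, called 6, and exact permutation of the mean scores over 924 assignments of the arrays, added after seeing the data, called 9. The preset correlation is liberal for these arrays, since among 100 splits of them, the real one included, the others gave a median of 5 and up to 12 called lists. Some of these splits kept most rats of a diet together. Splits with 3 PSC-fed rats in each group also gave up to 9 called lists.

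Few genes of fatty acid or sterol synthesis passed over all genes. In de novo lipogenesis, 2 of 21 measured members rose and 0 fell: Srebf1, from 9.31 ± 0.37 to 10.02 ± 0.17, and Dgat2, which completes triglyceride synthesis, from 9.94 ± 0.07 to 10.49 ± 0.28. Adjusted over the list alone 3 rose, with the elongase gene Elovl5 (0.28) added, and the list was not shifted (median log2 fold change 0.025, adjusted p = 0.389). In cholesterol synthesis and uptake, 2 of 21 fell and 0 rose, with 5 lower when adjusted over the list alone. Dhcr7 and Hsd17b7, late enzymes of the pathway, changed by -0.49 (SE 0.10) and -0.47 (SE 0.11), and Fdft1, Sqle and Msmo1, with -0.39, -0.43 and -0.39, passed over the list only. Hsd17b7 lost the threshold in 9 of the 12 fits without 1 array. This list shifted lower (median -0.13, adjusted p = 0.000695, and adjusted p = 0.548 with an estimated correlation). Hmgcs1 and Fasn were not analysed here.

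Lipoprotein genes shifted higher (median 0.15, adjusted p = 2.69e-05, and adjusted p = 0.151 with an estimated correlation), and their score was higher in all 6 PSC arrays than in any control. Apoa4, an apolipoprotein of triglyceride-rich particles, rose by 0.53 (SE 0.12, adjusted p = 0.035), the only 1 of 16 measured members to pass over all genes, and 9 rose when adjusted over the list alone. Apoa4 lost the threshold in 8 of the 12 fits without 1 array. Apoc1, Pltp and Apoc2 had values of 0.29, 0.33 and 0.22. Fatty acid oxidation and PPARa targets gave a mixed picture, with 2 of 29 higher and 3 lower, and 3 and 7 when adjusted over the list alone, among them Fgf21 (0.49). Cpt1a and Ppara, the nuclear receptor itself, rose, by 0.81 and 0.41, while its targets Vnn1 and Acot1 and the coactivator gene Ppargc1a changed by -0.72, -0.99 and -0.48. That list was not shifted (median -0.05, adjusted p = 0.118), and passed without control replicate 6, at 0.0282.

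Lipid droplet genes also moved in both directions. Fabp4, the droplet protein gene Cidea (from 9.32 ± 0.17 to 8.25 ± 0.51) and Lpl, which encodes lipoprotein lipase (-0.66), fell, and the lipase inhibitor gene G0s2 rose by 0.68. These were 3 lower and 1 higher of 18 measured members, or 4 and 2 when adjusted over the list alone, with Pnpla2 at -0.30 and Pparg at 0.35, and the list was not shifted (median 0.06, mean -0.09, adjusted p = 0.909). In bile acid synthesis and transport, 1 of 19 rose: Amacr, a racemase of side-chain oxidation, by 0.50 (SE 0.10). Adjusted over the list alone 2 rose, Amacr and the bile acid importer gene Slc10a1 (0.23), and 1 fell, the phospholipid exporter gene Abcb4, with -0.88 (SE 0.23) and an adjusted p of 0.0593 over all genes. The bile acid list was not shifted (median 0.0083, mean -0.05, adjusted p = 0.637).

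**Figure D3:**
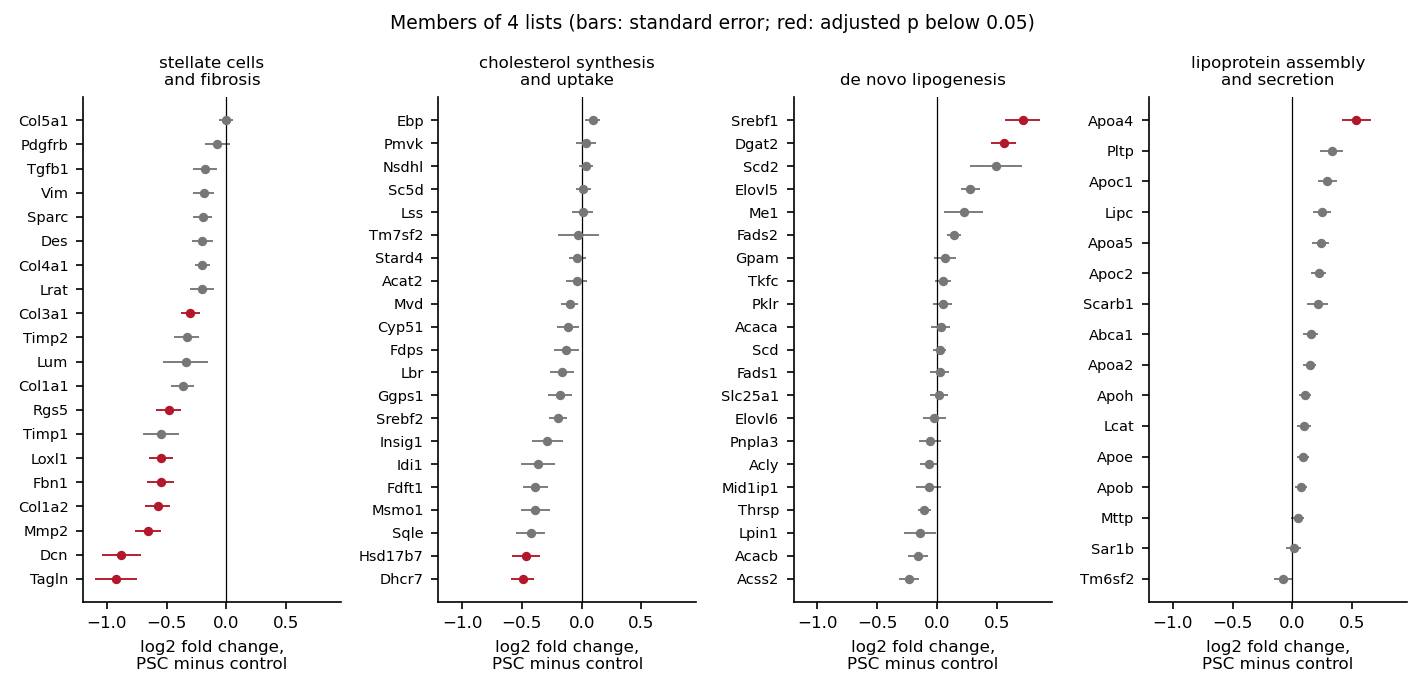
Log2 fold change, PSC minus control, with its standard error (horizontal) for every measured member of 4 lists (1 panel each, 1 gene per line); red marks an adjusted p below 0.05 over all genes tested. All 20 stellate and fibrosis markers lie below 0, Dhcr7 and Hsd17b7 lead the sterol genes downward, Srebf1 and Dgat2 rise, and 15 of 16 lipoprotein genes have values above 0.

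Amino acid breakdown and the urea cycle shifted higher (median 0.14, adjusted p = 0.00143, and adjusted p = 0.548 with an estimated correlation). Of 25 measured members 2 rose, Gpt and the histidine-degrading Uroc1 (0.37, SE 0.08), and 6 rose when adjusted over the list alone. Oat and Sds had values of 0.85 and 0.59 that did not pass over all genes. The amino acid response and ATF4 targets shifted lower (median -0.13, adjusted p = 0.0235, and adjusted p = 0.548 with an estimated correlation). Here 1 of 20 fell, the cysteinyl-tRNA synthetase gene Cars1 (-0.27, SE 0.06), and 2 fell when adjusted over the list alone, with Aldh18a1 at -0.36. This shift was lost without control replicate 6 (adjusted p = 0.065) or PSC replicate 6 (adjusted p = 0.0705).

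Heat shock genes shifted lower (median -0.15, adjusted p = 6.62e-05, and adjusted p = 0.195 with an estimated correlation). Hspb1, which encodes a small heat shock protein, fell from 5.18 ± 0.32 to 4.51 ± 0.16, as 1 of 16 measured members. Adjusted over the list alone 4 fell and 1 rose, the mitochondrial chaperonin gene Hspe1 (0.21), while Cryab, Hspb8 and Chordc1, with -0.39, -0.29 and -0.21, joined Hspb1. All 6 PSC arrays scored below every control. In the unfolded protein response 1 of 28 fell, the ER co-chaperone gene Dnajb9 (-0.46, SE 0.10), which was also the 1 member to pass when adjusted over the list alone. Atf3 and Hspa5 had -0.40 and -0.17. That list shifted lower (median -0.07, adjusted p = 0.0359, and adjusted p = 0.678 with an estimated correlation), and the shift was lost in 8 of the 12 fits that left out 1 array, with adjusted p up to 0.163 (without control replicate 1).

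Interferon response genes shifted lower (median -0.12, adjusted p = 2.69e-05, and adjusted p = 0.345 with an estimated correlation). Of 27 measured members 2 fell, Herc6 (-0.60, SE 0.09, adjusted p = 0.0041) and the guanylate-binding protein gene Gbp5 (-1.18, SE 0.28, adjusted p = 0.0394), and 4 fell when adjusted over the list alone. The other two were Mx2 and Ifi44l, with -0.51 and -0.21. Inflammation and NF-kB targets also shifted lower (median -0.035, mean -0.13, adjusted p = 0.0257, and adjusted p = 0.585 with an estimated correlation). Relb, an NF-kB subunit, and Birc3, an inhibitor of apoptosis, fell by 0.40 and 0.36 on the log2 scale, 2 of 23 members, and 8 fell and 1 rose when adjusted over the list alone. The chemokine gene Cxcl1 had -0.54. The call was lost without control replicate 4 (adjusted p = 0.107) or PSC replicate 1 (adjusted p = 0.0539). Among acute phase proteins 2 of 25 fell and 1 rose: Lbp, the lipopolysaccharide-binding protein gene, from 11.35 ± 0.18 to 10.48 ± 0.40, Orm1 by 0.37 on the log2 scale, and Lrg1 upward by 0.45. Adjusted over the list alone 3 fell, with Stat3 (-0.30) added, and 1 rose, and the list was not shifted (median -0.04, adjusted p = 0.126).

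Markers of lymphocytes shifted higher (median 0.19, adjusted p = 0.00165, and adjusted p = 0.151 with an estimated correlation). Nkg7, a gene of cytotoxic granules, rose from 4.64 ± 0.25 to 5.15 ± 0.16, as 1 of 17 measured members, and 7 rose when adjusted over the list alone. Prf1, Ccl5 and Cd79a had 0.38, 0.43 and 0.28. In this list all 6 PSC arrays scored above every control. Kupffer cell and macrophage markers shifted higher (median 0.20, adjusted p = 0.035, and adjusted p = 0.664 with an estimated correlation). Cd163 rose and Spp1, which encodes osteopontin, fell by 0.63 on the log2 scale, 1 of 21 members each way, with 6 and 2 when adjusted over the list alone. Vsig4 and Cd68 had 0.93 and 0.57. The macrophage shift was lost in 6 of the 12 fits without 1 array, with adjusted p up to 0.145 (without PSC replicate 3). Neutrophil markers were not shifted (0 of 14 passed over all genes or adjusted over the list alone, median -0.02, mean 0.0060, adjusted p = 0.909), nor were red cell markers (0 of 9 by either count, median -0.02, adjusted p = 0.461). S100a8 had -0.18, Il1r2 0.20, Tfrc -0.38 and Ahsp -0.28.

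Dim genes as a class had values above 0. When all genes were put in 6 classes of equal size by mean signal, the median log2 fold change was 0.05, 0.08 and 0.05 in the dimmer classes and -0.025, -0.045 and -0.027 in the brighter ones. Of the changed genes with a mean log2 signal up to 4.42, 32 were higher and 14 lower. The array-wide SD of log2 signals was 2.15 ± 0.014 in controls and 2.13 ± 0.017 in PSC-fed rats (n = 6, exact permutation p = 0.0216). Random lists with the mean signals of the lymphocyte list had a median of 0.04, and those with the signals of the pancreas list a median of 0.07. The medians of 4 called lists lay inside the middle 95% of such random lists: inflammation (percentile 16.2), pancreas (74.3), hepatocytes (92.6) and the unfolded protein response (3.17). The pancreas list was called by camera (median 0.09, adjusted p = 0.035, and adjusted p = 0.548 with an estimated correlation). Of its 15 measured members 0 passed over all genes or adjusted over the list alone, with Pnliprp1 and Try10 at 0.24 and 0.23, and the call was lost in 4 of the 12 fits without 1 array, with adjusted p up to 0.109 (without PSC replicate 5).

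**Figure D4:**
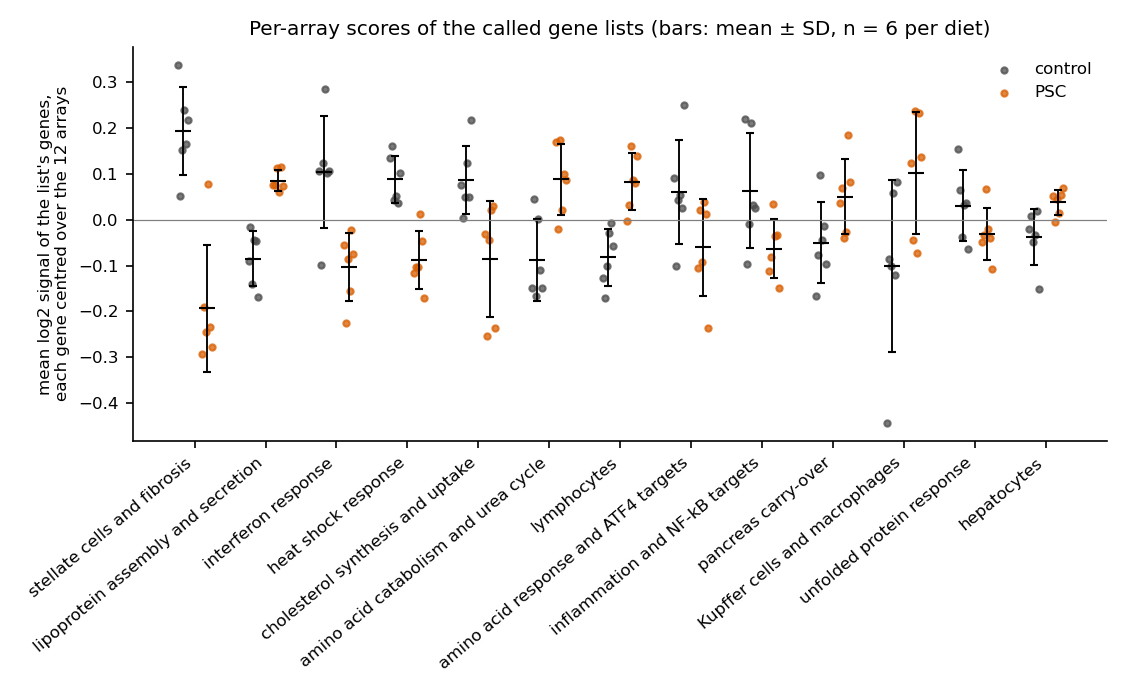
Per-array scores (vertical, mean log2 signal of a list's genes after centring each gene over the 12 arrays) for the 13 shifted lists along the horizontal axis; points are arrays, grey for control and orange for PSC, and bars give the mean ± SD of 6 arrays. All 6 PSC arrays lie beyond every control for lipoprotein, heat shock and lymphocyte genes, and PSC replicate 4 scores 0.0784 for the stellate list.

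Hepatocyte markers shifted higher by little (median 0.05, adjusted p = 0.0359, and adjusted p = 0.548 with an estimated correlation). Of 20 members 0 passed over all genes or adjusted over the list alone, Cyp2d3 and Apoa2 had 0.18 and 0.15, and the shift was lost in 6 of the 12 fits without 1 array, with adjusted p up to 0.0841 (without control replicate 3). Cholangiocyte markers were not shifted by camera (median 0.03, mean -0.09, adjusted p = 0.389), but all 6 PSC arrays scored below every control (exact permutation, adjusted p = 0.0179). Spp1 and the annexin gene Anxa4 (-0.41, SE 0.10) fell, 2 of 11 members, with 2 lower and 1 higher, Krt19 (0.27), when adjusted over the list alone. Endothelial markers were not shifted (0 of 12 passed, median -0.07, adjusted p = 0.561), with 1 higher (Stab1, 0.22) and 2 lower (Vwf, -0.32, and Ramp2, -0.28) when adjusted over the list alone. Adipose markers were not shifted (median 0.05, mean -0.07, adjusted p = 0.704). Fabp4 was the 1 of 12 that fell, and 2 fell and 1 rose when adjusted over the list alone, with Aqp7 at -0.32 and Cfd at 0.33.

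Genes of drug metabolism and oxidant defence changed in both directions. Of 19 AhR, CAR and PXR targets, Ugt2b1 rose and the carboxylesterase gene Ces2c (-0.99, SE 0.19) and Cyp3a18 (-1.12, SE 0.27) fell, that is 1 higher and 2 lower, or 1 and 6 when adjusted over the list alone, and the list was not shifted (median -0.0017, adjusted p = 0.704). Among NRF2 targets Gstm3 was the 1 of 23 that fell, by either adjustment, including when adjusted over the list alone (median -0.05, adjusted p = 0.22 for the list), and Abcc3 had -0.75. Of 18 antioxidant enzymes and metallothioneins, Gpx3 and Glrx fell by 0.49 and 0.25 on the log2 scale and Gpx1 rose by 0.29, with 2 lower and 3 higher, Sod3 (0.27) and Sod1 (0.15) added, when adjusted over the list alone (median 0, mean -0.04, adjusted p = 0.637 for the list).

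Neither list of sex-biased liver genes was shifted. Among 9 female-biased genes Sult2a1 rose and Cyp2c12 fell from 10.79 ± 0.28 to 9.91 ± 0.25, with 1 higher and 3 lower, Trim24 (-0.39) and Cyp2a1 (-0.23) added, when adjusted over the list alone (median -0.01, mean 0.15, adjusted p = 0.723 for the list). Probes for Cyp2c12 may also bind transcripts of close relatives. Its signal in these male controls was near that of Cyp2c13 (10.82). None of the 10 male-biased genes passed, 0 also when adjusted over the list alone, with Cyp2c13 and Cyp2a2 at 0.36 and 0.83 (median 0.07, adjusted p = 0.284 for the list). In the list of vitamin D and sterol side chain genes, Dhcr7 was the 1 of 10 that fell, also when adjusted over the list alone, and Vdr had 0.32 (median 0.10, adjusted p = 0.422 for the list).

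Lists of basic metabolic and cell processes did not pass the test. Gluconeogenesis and glycogen genes had 0 of 15 past the test over all genes, and 1 higher and 1 lower when adjusted over the list alone, with Gys2, the liver glycogen synthase gene, at -0.43 and Pck1 at 0.51 (median 0.08, adjusted p = 0.394). Oxidative phosphorylation had 0 of 27 by either count, with Ndufa1 and Ndufa8 at 0.20 and 0.12 (median 0.02, adjusted p = 0.422). Cell cycle genes had 0 of 27 by either count, with Mcm5 and Tyms at -0.31 and -0.26 (median -0.06, adjusted p = 0.277), and passed without control replicate 2, at 0.0158. Circadian clock genes had 0 of 17 by either count, with Bhlhe41 and Rora at -0.17 and -0.22 (median -0.05, adjusted p = 0.389). Median, mean and test differed in sign for 6 lists, those of cholangiocytes, neutrophils, adipose tissue, bile acids, lipid droplets and female-biased genes.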

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

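The loess values and the comparisons of PSC replicate 4 below were chosen after the results they bear on were seen. Among 282 groups of 6 values, 15 held an array far from the other 5 of its group, and chance alone marks about 1 in 20 groups, so that their number is about what chance gives.

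The score of stellate cell and fibrosis markers stayed within the range of the controls in 1 rat. PSC replicate 4 had a score of 0.0784 against -0.191 for the nearest of the other PSC arrays. In it Dcn, Mmp2 and Loxl1 lay below every control, whereas Col1a2, at 6.72, lay within the controls (6.68 to 7.06). A drift of signal with brightness between arrays does not account for the fall of the list, because its median lay at percentile 0 of 10000 random lists matched on mean signal, and after cyclic loess it was still lower (median -0.32, adjusted p = 8.52e-12). The list's call without loess is lost with an estimated correlation (adjusted p = 0.151). The stellate score moved from the mean of the Kupffer and endothelial scores by -0.474 (exact permutation p = 0.00216). The stellate score alone had an exact permutation p of 0.00433. The comparison therefore cannot decide on a smaller share of all cells other than hepatocytes. Neither of the other scores fell like it: the Kupffer score rose by 0.204 and the endothelial score changed by -0.029 (exact permutation, adjusted p = 0.115 and 0.557). The cholangiocyte score fell too, by 0.0895, with Spp1 and Anxa4 at -0.63 and -0.41. Of its 11 members 6 had values above 0 (median 0.03), but random lists matched on mean signal also had a median of 0.03. After cyclic loess the list's median was -0.03 (camera, adjusted p = 0.181). That score therefore does not decide on a smaller share of cholangiocytes. A smaller share of more than 1 cell type stays open. A diet effect on stellate cells or on their matrix genes and differences in the piece of liver sampled also stay open, as neither was tested.

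PSC replicate 4 also stood high for bile acid synthesis and transport, with a score of 0.225 against -0.0458 for the nearest PSC array, and for the transporter gene Abcc3, at 7.12. On the same array the lipoprotein score of 0.061 and the lymphocyte score of 0.0853 lay above every control. It correlated at 0.994 with the controls and at 0.992 with the other PSC arrays.

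Control replicate 6 was low for Inhbc (7.96, nearest 8.71), Cpt1a (8.41, nearest 9.26), Apoc1 (11.17, nearest 11.53), Dgat2 (9.80, nearest 9.94) and Cyp2a2 (8.15, nearest 10.03). Without it the changes of Inhbc, Cpt1a and Dgat2 stayed past the threshold. Control replicate 2 was low for Mx2 (7.13), Aldh18a1 (5.36) and Lbp (10.99), and high in its oxidative phosphorylation score (0.0957). Control replicate 1 was low for Cd163, at 4.96 where the other controls lay at 6.04 or above. PSC replicate 1 was low for Hspb1 (4.19, nearest 4.51) and high for Rora (8.41, nearest 8.07).

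Outside the genes tested, 49 transcript clusters without a gene symbol of their own in the table used changed when all clusters were tested.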

How the results depend on the processing

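Cyclic loess, leaving out PSC replicates 2 and 5 together and the permutation of list scores were chosen after seeing the data. No called list or called named gene changed sign in any setting run, falls outnumbered rises in the counts of changed genes and of genes at a fold of 1.3 in all settings run, and the separation of the diets had an exact p between 0.00216 and 0.00952. Of the 53 named genes past the threshold 20 stayed past it in every setting, and over all settings 935 of 1164 values did. Among changed list members Gbp5 lost it in 10 of the 12 fits without 1 array, Relb, Birc3, Anxa4 and Hsd17b7 in 9, and Apoa4 and Glrx in 8. Orm1 lost it in 7, Dnajb9 in 6, Cars1 in 5, Uroc1, Nkg7 and Spp1 in 4, and Amacr and Ces2c in 1. Where no reason is given, the cause was not tested. With 11261 transcript clusters unnamed, dim signals compressed by RMA and no detection calls, small changes of dim genes are the least certain.

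The main count of 473 changed genes became 253 of all transcript clusters (56 higher, 197 lower), where more clusters were tested. Without the dimmest genes it was 711 (539 lower), at an adjusted p below 0.1 it was 1140 (402 higher, 738 lower), and without PSC replicates 2 and 5, with fewer arrays, 225 (59 higher, 166 lower). Without 1 array it ran from 142 (29 higher, 113 lower; without control replicate 1) to 735 (192 higher, 543 lower; without PSC replicate 4). In the remaining settings, apart from the replicate block below, it lay between 422 and 687. Genes at a fold of 1.3 became 801 (298 higher) over all clusters, and 160 (42 higher, 118 lower) at a fold of 1.5.

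Replicate numbers do not pair the arrays: deviations of the 6 same-numbered pairs correlated at -0.151 to 0.111, only 1 pair above 0.1, and 1 control and 1 PSC array matched its own number best. With the replicate number as a block, which uses up degrees of freedom, 94 genes passed (16 higher, 78 lower), and the hepatocyte list had an adjusted p of 0.0731, while no other list's call changed.

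Of 13 called lists, 0 were called with an estimated correlation and 6 by fry, and 8 to 12 without 1 array (8 without PSC replicate 6). With an estimated correlation the adjusted p was 0.151 for the stellate, lipoprotein and lymphocyte lists, 0.195 for heat shock, 0.345 for interferon, 0.585 for inflammation, 0.664 for Kupffer cells and 0.678 for the unfolded protein response. It was 0.548 for the cholesterol, ATF4, amino acid catabolism, pancreas and hepatocyte lists. Fry, which tests each list alone, gave 0.102 for cholesterol, 0.0563 for amino acid catabolism, 0.164 for pancreas, 0.176 for ATF4, 0.199 for inflammation, 0.248 for Kupffer cells and 0.279 for the unfolded protein response. Permutation of scores gave 0.115 for Kupffer cells, 0.122 for inflammation, 0.133 for ATF4, 0.143 for pancreas and 0.224 for the unfolded protein response, and 0.0179 for cholangiocytes, lower.

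Other settings ended 5 list calls. Without the dimmest genes the unfolded protein response had 0.220, ATF4 0.171 and inflammation 0.0532. Quantile normalization again gave 0.101 for the unfolded protein response, 0.232 for pancreas and 0.0634 for hepatocytes, and cyclic loess 0.140, 0.211 and 0.140. Without PSC replicates 2 and 5 the unfolded protein response had 0.110 and pancreas 0.148, and array weights gave pancreas 0.0586. Newly past the threshold were acute phase proteins (0.0229) and oxidative phosphorylation (0.0489) after loess, and fatty acid oxidation over all clusters (0.04997).

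Leaving out 1 array gave adjusted p from 0.00467 to 0.163 for the unfolded protein response, 0.00390 to 0.0705 for ATF4, 0.00440 to 0.107 for inflammation and 0.00661 to 0.145 for Kupffer cells. The ranges were 0.0107 to 0.109 for pancreas, 0.0183 to 0.0841 for hepatocytes, 0.0282 to 0.244 for fatty acid oxidation and 0.0158 to 0.744 for cell cycle. The other 7 called lists stayed called without any 1 array.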

Other observations

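The gene families below and the test of the difference between the lipogenesis and cholesterol lists were chosen after their values were seen. The remaining tests were chosen before their own values were seen, apart from the loess normalization they use. Those on the lymphocyte markers and on the surplus of falls were set up for patterns already seen.

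Of 54 genes of the cytochrome P450 families Cyp1 to Cyp4, 5 fell and 1 rose. Cyp4f4 rose from 9.30 ± 0.10 to 9.77 ± 0.15 (log2 signal ± SD, n = 6), while Cyp4f5, its relative, changed by -0.41, Cyp2j4 by -0.46, Cyp2c12 by -0.88, Cyp3a18 by -1.12 and Cyp2c55 by -2.49. Among 20 glutathione transferase genes Gstp3 rose and Gstm3 fell. MicroRNA genes had 7 of 363 higher and 1 lower, and olfactory receptor genes 5 of 1117 higher and 0 lower, at a median log2 signal of 3.29 and 2.68.

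Genes that changed the same way lay next to each other more often than shuffled calls did. There were 15 such neighbouring pairs, against a mean of 7.34 and a 95th percentile of 12 over 10000 shuffles (permutation p = 0.0069). The shuffles did not hold brightness fixed. Yet the dimmest of the 6 classes by mean signal held 14 rises and 2 falls, and the brightest 46 and 95. Whether like brightness of neighbours adds to the pairs was not tested. The matrix genes Ogn, Omd and Aspn, neighbours in a cluster of small leucine-rich proteoglycans, changed by -0.37, -0.71 and -0.72. The keratin genes Krt8 and Krt18 of epithelial cells changed by -0.54 and -0.53, and the caspase genes Casp4 and Casp12 by -0.36 and -1.38. Shared regulation of neighbours may be 1 reason, and probes that bind several members of a duplicated family may be another, which the 15 pairs do not separate.

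The difference between the lipogenesis and cholesterol scores was 0.258 larger in PSC-fed rats (exact permutation p = 0.013). Most of it, 0.172, is the fall of the cholesterol score, and the call of that list is lost with an estimated correlation (adjusted p = 0.548). The lipogenesis score alone had an exact permutation p of 0.143, and no biological explanation was tested.

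The rise of lymphocyte markers was weighed against technical sources. Their median lay at percentile 100 of random lists matched on mean signal, and after cyclic loess the list was still higher (adjusted p = 0.00963), which argues against a drift of signal with brightness as the whole source. The median log2 fold change went from 0.185 to 0.127 with loess, and the matched random lists had 0.043, so that part of the rise goes with brightness. The list's call without loess is lost with an estimated correlation (adjusted p = 0.151). The lymphocyte score moved from the mean of the red cell and neutrophil scores by 0.202 (exact permutation p = 0.00216). The lymphocyte score alone had the same p, so this comparison cannot decide on more blood in the tissue. Only 9 of 17 red cell markers were measured. In controls Ahsp (3.9) and the neutrophil marker S100a8 (2.4) were dim, though Tfrc (8.5) was not. More lymphocytes in the livers of PSC-fed rats and more expression per cell stay open, as neither was tested.

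More genes fell than rose, 72.5% of those changed, except among those with a mean log2 signal up to 4.42, with 32 higher and 14 lower. After cyclic loess, which removes a drift of signal with brightness, 68.1% of 423 changed genes fell, so such a drift alone does not account for the imbalance. What else could cause it, such as a smaller share of some cell types, was not separated here.

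Chance assignment of the arrays is argued against for the counts of changed genes and of genes at a fold of 1.3. For called lists it stays open, as the margin was 1 list and only 100 of the 462 splits were run. Of 100 splits of the arrays into groups of 6, the real one included, 1 gave as many changed genes, the real one with 473, and the highest other split gave 1. For genes at a fold of 1.3 it was also 1 of 100, with 501 against 317 in the highest other split and a median of 47. For called lists it was 1 of 100, with 13 against 12 and a median of 5. The other splits with 12 lists put 4, 2 and 5 of the 6 PSC-fed rats in the group called PSC. The split with 317 genes put 4 there. Such splits keep part of the diet contrast, so they do not show what chance alone gives. Among splits with 3 PSC-fed rats in each group the highest gave 9 lists. That count rests on the preset correlation, and 0 lists were called with an estimated one. Without 1 array 8 to 12 lists were called, no more than the 12 of the highest other split.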
